A study of Rattus norvegicus with 8 samples.

How the data were processed

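Liver RNA of 8 male Sprague-Dawley rats aged 7 weeks was measured on Affymetrix 3' expression arrays, 1 array per rat. Per the series' design text, 2 groups of 11 rats received a commercial rodent diet (CRF-1) with 10 g cholesterol and 5 g cholic acid per kg for 2 weeks. The second group also received 10 g per kg of freeze-dried live Lactobacillus brevis 119-2, a lactic acid bacterium isolated from turnip. Arrays of 4 rats per group were analysed here. The source label of the control arrays names the CRF-1 diet alone, whereas the design text gives the control rats the cholesterol and cholic acid version, and the design text was followed. The labels call the 4 samples of a group biological replicates. Per the labels' protocols, total RNA was extracted with Trizol, purified with a column kit and turned into biotin-labelled RNA with a 3' in vitro transcription kit.

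The deposited table holds one log2 value per probe set and array, already normalized by the authors. The method of summarisation and normalization is not given in the sources used here, and neither are scan dates or other batches. Array medians lay between 6.61 and 6.63. A feature of the deposited values limits every comparison: 24719 of the 31042 probe sets held 1 value on all 8 arrays to within 0.01 log2, and 24452 of them to within 1e-06. Such a value was set by the processing and does not show that the gene's level was the same in all rats. The other 6323 probe sets, 20.4%, are called varying below, and 4882 of these had exactly 1 gene symbol. The 0.01 log2 limit was chosen after the data were seen. Background flags of single probe sets were not used here, and the number of arrays limits the precision.

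The table had 31099 probe sets, of which 57 Affymetrix controls were left out of the tests. In the platform annotation 20826 of the remaining probe sets had 1 gene symbol, 436 had several and 9780 had none. Symbols were updated through gene identifiers. Each of the 14217 genes was represented by the probe set with the highest mean over the 8 arrays among those with exactly 1 symbol. Over the varying probe sets no 2 arrays of a group shared an identical value. The SD of the difference between 2 arrays of a group ranged from 0.401 to 0.817 log2 over the varying probe sets.

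The comparison, L. brevis minus control, was fitted to all 31042 probe sets with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The samples, the test, the gene lists, the genes to be named and most alternatives were fixed before the data were examined. A fit to the varying probe sets alone was added afterwards, and its counts stand beside those of the planned fit. On simulated data with 200 probe sets shifted by 1 log2 unit, the fit to all probe sets recovered 43.5% of them with 11 false calls, and 81.5% with 8 false calls at 2 log2 units. The fit to varying probe sets recovered 64% with 4 false calls and 94% with 12 false calls. The shifted probe sets were drawn from varying ones with a mean above the median of all probe sets, so these shares do not hold for flat or dim ones. In the fit to all probe sets at 1 log2 unit, 11 false calls stood beside 87 recovered. That is a larger false share than the threshold of 0.05 aims at. The simulated probe sets varied independently of one another.

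Fixed lists of 29 gene groups were tested with limma's camera at its preset correlation of 0.01. Beside it stood camera with an estimated correlation (statmod 1.5.0), fry, and an exact permutation test over all 70 assignments of each rat's mean over a list. The lists were cholesterol synthesis, sterol uptake and SREBP control, LXR targets and sterol export, bile acid synthesis, bile acid transport and sensing, cholesterol ester and lipoprotein, fatty acid and triglyceride synthesis, PPAR-alpha targets and fatty acid oxidation, gluconeogenesis and glycolysis, xenobiotic metabolism, growth hormone and sex-biased liver genes, acute phase response, inflammatory signalling, interferon-stimulated genes, unfolded protein response, oxidative stress response, heat shock and immediate early genes, cell cycle, circadian clock, oxidative phosphorylation and ribosomal proteins. Cell type lists were macrophage and Kupffer cell, lymphocyte and antigen presentation, stellate cell and fibrosis, cholangiocyte, sinusoidal and vascular endothelium, erythroid and platelet, pancreas and adipose, and hepatocyte secretory proteins. Camera ran on all measured members, while the median given for a list covers its varying members, a choice made after the data were seen. Since members that do not vary carry no measured difference but count in camera's direction, camera was also run on the varying members alone, again after the data were seen. In simulations over 14217 genes, camera called a list shifted by 0.3 log2 in 20 of 20 runs and an unshifted list in 0 of 20. The simulated genes varied independently of one another. These runs therefore cannot show how often camera at its preset correlation makes false calls where the genes of a list vary together.

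The rule for named genes had 3 parts. Part 1 took up to 12 genes per direction by size of change among those past the threshold, filled by smallest unadjusted p, with a mean above the median of all probe sets and exactly 1 symbol. Part 2 fixed 12 genes of cholesterol and bile acid metabolism, of which 8 were measured. Part 3 took up to 4 members of each list past the threshold or, where none passed, the 2 with the smallest unadjusted p. Because most calls of the planned fit fell on probe sets that did not vary, part 1 was applied within the varying probe sets, an amendment made after the data were seen. Any gene outside this rule is said to have been chosen after its values were seen.

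Signs of RNA and labelling quality were taken from the Affymetrix control probe sets: the 5' minus 3' signal of GAPDH and actin, the poly-A spikes added to the RNA before labelling, and the hybridisation spikes. Group differences in these were tested by exact permutation, two-sided, and Pearson and Spearman correlations by permutation. Alternatives fixed in advance were quantile normalization, median centring, removal of dim probe sets below the 40th percentile, no intensity trend, a robust trend, array weights, a replicate block, each replicate left out, a threshold of 0.1, rank product and the mean of all probe sets of a gene. Added after the data were seen were the fit to varying probe sets, GAPDH 5' minus 3' signal as a covariate, arrays matched on that signal, and a fit without L. brevis arrays 3 and 4. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.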

Results

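The data were 8 liver expression arrays, 4 from rats on a cholesterol and cholic acid diet (control) and 4 from rats on that diet with freeze-dried Lactobacillus brevis 119-2. The series is about the effect of this strain on cholesterol in the liver, so the comparison asks which liver genes, above all those of sterol and bile acid metabolism, differed between the diets. Values are log2 signals as deposited, and differences are L. brevis minus control.

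Livers of rats fed L. brevis had less signal of Icoslg and Krt79. Icoslg, which encodes the ligand of the T cell costimulator ICOS, fell by 0.89 on the log2 scale, from 9.16 ± 0.08 to 8.27 ± 0.14 (SD, n = 4 each), 1.85-fold lower (adjusted p = 0.0207, limma). Krt79, a type II keratin, fell by 0.61, from 8.02 ± 0.05 to 7.41 ± 0.08, 1.52-fold lower (adjusted p = 0.0103). Calls on probe sets that did not vary lowered both adjusted p values, and over varying probe sets alone each was 0.0383 (limma). Markers of endothelial cells were lower as a group, with a median of -0.41 over 9 varying members, all 9 of them lower (camera adjusted p = 0.00916), a call lost with fry, without control 1 or L. brevis 1 and with an estimated correlation (adjusted p = 0.707 with an estimated correlation). No gene of cholesterol synthesis, sterol export or bile acid synthesis passed the test, although Scd, the desaturase that makes monounsaturated fatty acids, was far higher in 3 of the 4 L. brevis livers. Icoslg and Krt79 kept their direction but lost the adjusted threshold under quantile normalization (adjusted p = 0.0653 and 0.0582), under median centring (0.0706 and 0.0574) and with the GAPDH 5' minus 3' signal as a covariate (-0.82 and -0.54, adjusted p = 0.419 for both), as well as without L. brevis 3 and 4 (-0.83 and -0.57, adjusted p = 0.303 for both). A replicate block in the fit ended both calls as well, with the same differences (adjusted p = 0.255 and 0.133, limma). Leaving out any 1 of control 2, 3 or 4 or L. brevis 2, 3 or 4 also ended the Icoslg call (adjusted p from 0.0510 to 0.0703), with differences from -0.85 to -0.88.

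**Figure D1:**
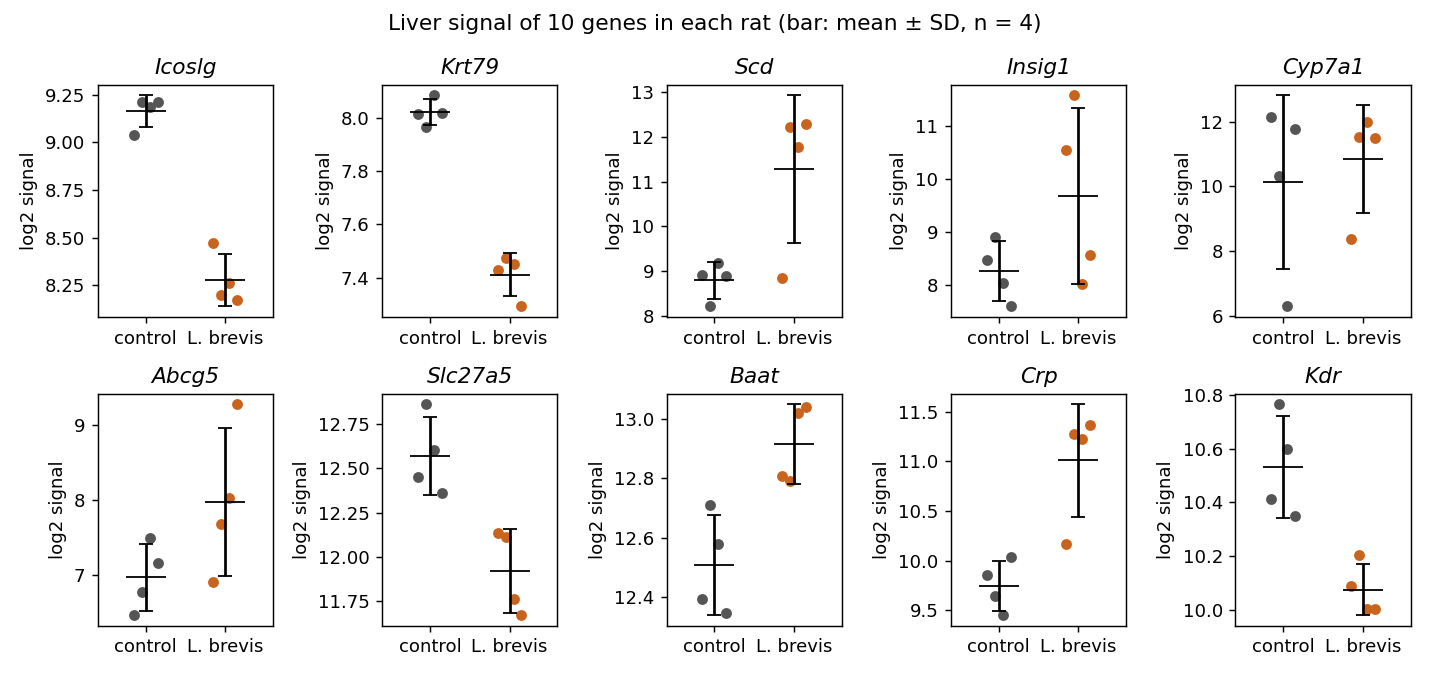
Log2 signal of 10 genes in each of the 8 livers (points), with the mean and SD of each diet (bars, n = 4). Icoslg and Krt79 were the only genes of the 10 past the adjusted threshold, and the L. brevis rats were spread widely for Scd, from 8.83 to 12.29.

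Over all 31042 probe sets, 17 were higher and 27 lower at an adjusted p under 0.05. However, 37 of these 44 did not vary (largest difference 1.025e-07 log2), which leaves 1 higher and 6 lower probe sets with a measurable difference. Most of the 37 had smaller p values than any of these 7. Since the adjustment goes by rank, they lowered the adjusted p of the 7, which therefore cannot be read apart from them. Besides Icoslg and Krt79 these were RT1-CE5, a class I histocompatibility gene, at +0.15 (SE 0.01, adjusted p = 0.0207), and 4 lower probe sets without a single gene symbol, all named or counted after their values were seen. The largest of the 4 differences was -1.53 (SE 0.15, adjusted p = 0.0280). When only the 6323 varying probe sets were tested, 0 were higher and 4 lower by limma, namely Icoslg, Krt79 and 2 of the probe sets without a symbol, each with an adjusted p of 0.0383. RT1-CE5 was not called in that fit (adjusted p = 0.106). In that fit 1548 probe sets had an unadjusted p under 0.05, and rank product over all probe sets called 704 higher and 616 lower. In the planned fit 1450 of the varying probe sets (22.9%) had an unadjusted p under 0.05, 597 of them higher and 853 lower. The diets did not overlap in 714 varying probe sets, 11.3%, where chance gives 2.86%.

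Of the 12 genes next in order on the higher side, none passed the adjusted threshold and all had 4 L. brevis values above the 4 control values. Their choice by smallest unadjusted p makes such a separation likely, so it is no further support for a difference. Rasa1, a negative regulator of Ras, differed by +0.90 (SE 0.14), with +0.09 at its other varying probe set. Cpd, a carboxypeptidase of the secretory pathway, differed by +0.87 (SE 0.15). The nuclear receptor gene Rora stood at +0.86 (SE 0.11) and Srp72, a subunit of the signal recognition particle, at +0.80 (SE 0.13). Smaller differences were those of C11h21orf91 (+0.64), Cyfip1 (+0.42), Hikeshi (+0.39), Sar1b (+0.37), Mrps33 (+0.27), C19h16orf87 (+0.26), Pold4 (+0.15) and Apmap (+0.12). Sar1b encodes a GTPase of the vesicles that carry lipoproteins out of the endoplasmic reticulum. Hikeshi, a nuclear import factor for heat shock proteins, had the smallest adjusted p of these genes, 0.0962. Single rats decided some of these calls: without control 4 the threshold was passed by Rasa1 (+1.04, adjusted p = 0.00389), Srp72 (+0.92), Cyfip1 (+0.48) and Hikeshi (+0.42), without control 2 by Sar1b (+0.42), and without control 3 by Hikeshi (+0.35). With array weights, which counted L. brevis 3 most (3.36) and L. brevis 1 least (0.32), Hikeshi (+0.41) and Pold4 (+0.15) passed it.

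On the lower side, Slc25a28, a mitochondrial iron carrier, differed by -0.71 (SE 0.09, adjusted p = 0.0941) and Inhba, the subunit of activin A, by -0.71 (SE 0.09, adjusted p = 0.106). Fam171a1 came closest to the threshold at -0.40 (SE 0.04, adjusted p = 0.0599). Tmed9, a cargo receptor between the endoplasmic reticulum and the Golgi, stood at -0.35 (SE 0.04, adjusted p = 0.0772). The others were 4933427D14Rikl (-0.54), Ogfod3 (-0.46), Wdr81 (-0.35), Cc2d1b (-0.35), Grb14, an inhibitor of insulin receptor signalling (-0.35), and Prkch, a protein kinase C (-0.34). The threshold was passed without L. brevis 3 by Fam171a1 (-0.43), Tmed9 (-0.38) and Cc2d1b (-0.38), without L. brevis 1 by Slc25a28 (-0.79) and 4933427D14Rikl (-0.59), and without control 4 by Wdr81 (-0.38). With the same array weights it was passed by Slc25a28 (-0.78, adjusted p = 0.00656), Inhba (-0.73, adjusted p = 0.0398), 4933427D14Rikl (-0.60) and Wdr81 (-0.33). A replicate block brought Fam171a1 (adjusted p = 0.0108) and Inhba (adjusted p = 0.0389) past it.

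No list of sterol metabolism passed the test. Of 18 measured cholesterol synthesis genes 5 varied, 1 higher and 4 lower, with none at an unadjusted p under 0.05 and a median of -0.07 (camera adjusted p = 0.808, and 0.778 over varying members alone). That median ran from -0.22 without control 4 to -0.017 without control 1, and was +0.13 with the GAPDH 5' minus 3' signal as a covariate. The last enzymes of the pathway, Dhcr7 and Sc5d, differed by -0.48 (SE 0.23) and -0.21 (SE 0.13), and the other varying probe sets of Sc5d by +0.25 and -0.13. At the brightest Sc5d probe set control 1 had 10.02, against 9.61 to 9.72 in the other controls. Sqle and Srebf2 held single values of 6.10 and 7.79 on all arrays, so no difference could be measured for them. In the list of sterol uptake and SREBP control, 6 of 9 genes varied, 3 in each direction, with a median of -0.01 but a mean of +0.16 (camera adjusted p = 0.622, and 0.968 over varying members alone). Insig1, which retains SREBP in the endoplasmic reticulum, differed by +1.42 (SE 0.87), from 8.26 ± 0.57 to 9.68 ± 1.66, and by +0.79 without L. brevis 2. The lipoprotein receptor gene Lrp1 differed by -0.30 (SE 0.09) and was the only member at an unadjusted p under 0.05. Among LXR targets and sterol exporters 10 of 13 varied, 7 higher and 3 lower, none at an unadjusted p under 0.05 (median 0.05, camera adjusted p = 0.622). That median was 0.014 without control 2 and -0.038 without L. brevis 3 and 4. The sterol exporter gene Abcg5 differed by +1.00 (SE 0.54), or +0.57 without L. brevis 4, and lipoprotein lipase, Lpl, by -0.67 (SE 0.36), while Abcg8 held 6.18 throughout. In the cholesterol ester and lipoprotein list 5 varying genes were higher and 6 lower, with Lipc, hepatic lipase, at +0.22 (SE 0.09) and Apoa1 at -0.13 (SE 0.06). That list had 17 measured members, 1 at an unadjusted p under 0.05, a median of -0.02 and camera pointing up (adjusted p = 0.757), but down under quantile normalization (adjusted p = 0.0331, and 0.780 with an estimated correlation). The medians of the lists of sterol uptake and of cholesterol ester and lipoprotein changed sign with single rats left out, from -0.085 to 0.036 and from -0.0031 to 0.021. None of the 7 lists called under quantile normalization was called there over its varying members alone.

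Bile acid genes had more members on the higher side, with no list past the test. In bile acid synthesis 9 of 13 varying genes were higher and 4 lower, with 3 higher and 1 lower at an unadjusted p under 0.05 and a median of 0.16 (camera adjusted p = 0.252). That median was 0.065 without control 3, 0.11 without L. brevis 3, 0.029 with the GAPDH 5' minus 3' signal as a covariate and -0.0086 without L. brevis 3 and 4. Cyp7a1, the rate-limiting enzyme of the pathway, spanned 6.31 to 12.13 in control rats and 8.38 to 11.98 in L. brevis rats, so that its difference of +0.71 (SE 1.55) was far inside the spread between rats, and was -0.56 without control 3. Cyp8b1, needed to make cholic acid, differed by -0.35 (SE 0.65), or +0.068 without L. brevis 2. The last steps of the pathway differed in opposite directions: Slc27a5, which activates bile acids with coenzyme A, by -0.65 (SE 0.16, adjusted p = 0.323) and Baat, which joins them to taurine or glycine, by +0.41 (SE 0.11, adjusted p = 0.347). Of the transport and sensing genes 8 of 13 varying members were higher and 5 lower, 1 of each at an unadjusted p under 0.05, with a median of 0.17 (camera adjusted p = 0.30). It turned to -0.023 without control 1, -0.014 without L. brevis 4 and -0.093 with the GAPDH covariate. Nr1h4, the bile acid receptor FXR, differed by -0.54 (SE 0.19), its target Nr0b2 by +0.45 (SE 0.37), or +0.21 without L. brevis 2, and the uptake transporter gene Slc10a1 by +0.28 (SE 0.10).

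In fatty acid and triglyceride synthesis 5 of 13 varying genes were higher and 8 lower, with 1 higher and 2 lower at an unadjusted p under 0.05. The list's median was -0.03 and its mean +0.18, and camera gave no call (adjusted p = 0.804), while the median was 0.044 without control 3 and 0.062 without L. brevis 2. Scd, singled out after its values were seen, had 8.79 ± 0.41 in control and 11.28 ± 1.65 in L. brevis livers, a difference of +2.49 (SE 0.84, adjusted p = 0.352). L. brevis 1 had 8.83, inside the control range, and L. brevis 2 to 4 had 12.22, 11.77 and 12.29. The lipogenic factor gene Mlxipl (ChREBP) and Acaca, acetyl-CoA carboxylase, differed by -0.35 (SE 0.09) and -0.34 (SE 0.09). PPAR-alpha targets had 7 varying members higher and 15 lower, with 1 higher at an unadjusted p under 0.05, a median of -0.20 and camera pointing up (adjusted p = 0.543), but down under quantile normalization (adjusted p = 0.0312, and 0.993 with an estimated correlation). Hadhb, of mitochondrial fatty acid oxidation, stood at +0.72 (SE 0.19) and Cyp4a3 at +0.42 (SE 0.19). With the GAPDH 5' minus 3' signal as a covariate that list's median was 0.55 (adjusted p = 4.66e-09, and 0.968 with an estimated correlation), and it was 0.21 without L. brevis 3 and 4 (adjusted p = 0.0213, and 0.977 with an estimated correlation) and 0.037 without L. brevis 4. Gluconeogenesis and glycolysis had 5 higher and 7 lower (median -0.03, or 0.011 without L. brevis 2, camera pointing up, adjusted p = 0.622), with the glucose transporter gene Slc2a2 at +0.55 (SE 0.17), the only member at an unadjusted p under 0.05, and Igfbp1 at -1.35 (SE 0.72).

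Endothelial markers were the only list of the 29 past the test over all members. All 9 varying members of 15 measured were lower, 3 of them at an unadjusted p under 0.05, with a median of -0.41 (camera adjusted p = 0.00916, and 0.0407 over varying members alone), although 0 members passed over all genes and 3 passed adjusted over the list alone by limma, 1 of these at a probe set that did not vary. The call was lost with an estimated correlation (adjusted p = 0.707) and with fry (adjusted p = 0.293). By exact permutation of the rats' means every L. brevis mean lay below every control mean (exact p = 0.0286, the smallest 4 against 4 can give), a p that adjustment over the 29 lists leaves at 0.654, so the adjusted value says little. Kdr, the VEGF receptor 2, differed by -0.46 (SE 0.10, adjusted p = 0.293), with +0.02 at its other varying probe set, Pecam1 by -0.26 (SE 0.06) and the scavenger receptor gene Stab1, named after its values were seen, by -0.83 (SE 0.30). The median was -0.36 with the GAPDH 5' minus 3' signal as a covariate. Without control 1 the median was -0.34 and without L. brevis 1 it was -0.46, and either omission ended the call (adjusted p = 0.0744 and 0.0568). Without control 2 the median was -0.25, with a call over all members (adjusted p = 0.0248) but none over varying members alone (0.0715).

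**Figure D2:**
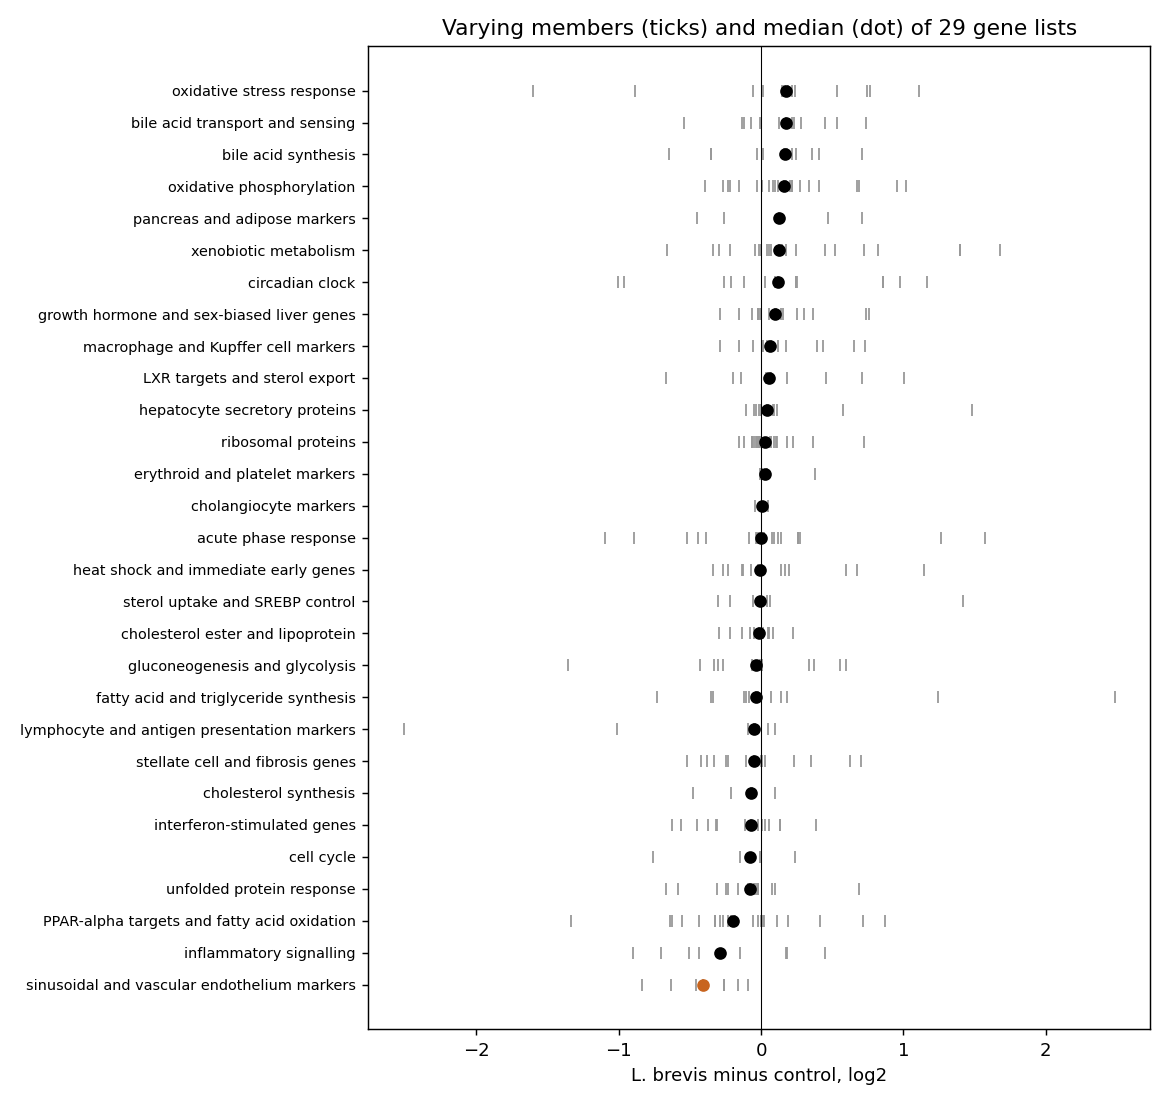
Difference between diets (x axis, L. brevis minus control, log2) for the varying members (ticks) of each of the 29 gene lists, with the list's median (dot, orange where camera passed the adjusted threshold at its preset correlation). All 9 endothelial ticks lie below 0, and the other lists have members on both sides.

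No list of other cell type markers passed the test on all 8 arrays. For all 28 other lists 0 members passed over all genes by limma, and 0 passed adjusted over the list alone. Macrophage and Kupffer cell markers had 11 varying members higher and 3 lower, 2 of them at an unadjusted p under 0.05 (median 0.06, camera adjusted p = 0.251), with Adgre1 at +0.65 (SE 0.17) and C1qb, a complement subunit, at +0.73 (SE 0.28). That list passed camera without control 2 (median 0.19, adjusted p = 0.00875) and without L. brevis 2 (median 0.12, adjusted p just under 0.05), calls lost with an estimated correlation (adjusted p = 0.370 and 0.703 with an estimated correlation). Its median was 0.017 without L. brevis 1. Stellate cell and fibrosis genes had 6 higher and 9 lower, 2 of each at an unadjusted p under 0.05 (median -0.05, but 0.049 without control 2, 0.025 without L. brevis 1 and 0.016 without L. brevis 3, camera adjusted p = 0.804, and 0.968 over varying members alone), with Loxl2 at +0.23 and Col6a3 at -0.33. Of the lymphocyte and antigen presentation markers 2 varying members were higher and 5 lower, with none at an unadjusted p under 0.05. The median of that list was -0.05 and its mean -0.51, without a call (camera adjusted p = 0.30, and 0.968 pointing down over the 7 varying members alone), and the median was 0.0069 without L. brevis 4. That mean includes the class II genes RT1-Ba and RT1-Bb, which differed by -2.51 (SE 1.88) and -1.01 (SE 0.85). Other probe sets gave +2.31, -2.91 and -0.07 for RT1-Ba and +1.68 for RT1-Bb, some of them in the opposite direction. The mean of -0.51 therefore cannot be read as a level of lymphocytes. Cholangiocyte markers had 2 varying members, Cldn7 at -0.04 and Epcam at +0.05 (camera adjusted p = 0.622, none at an unadjusted p under 0.05). Erythroid and platelet markers had 3 higher and 1 lower, with Hbb at +0.38 and Slc4a1 at +0.04 (median 0.02, but -0.31 without L. brevis 2 and -0.056 without control 1, camera adjusted p = 0.528). Hbb was 14.31 in L. brevis 2, 11.24 to 12.55 in the other L. brevis rats and 11.66 to 12.93 in control rats. Pancreas and adipose markers had 3 higher and 2 lower, with Cela1 at -0.45 and Cfd at +0.47 (median 0.13, or 0.032 without L. brevis 3, camera adjusted p = 0.622). Cfd was 8.61 in L. brevis 3 (other L. brevis rats 7.27 to 8.12) and Cela1 9.22 in control 1 (other controls 8.30 to 8.72). Hepatocyte secretory proteins had 8 higher and 5 lower (median 0.04, camera pointing up, adjusted p = 0.252, but down under quantile normalization, 0.00595, and 0.801 with an estimated correlation), with the urea cycle gene Otc at +1.48 (SE 0.70) and Gc at +0.04, where another probe set of Gc gave +0.67. None of these last 3 lists had a member at an unadjusted p under 0.05.

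No list of inflammatory genes passed the test on all 8 arrays. The acute phase list had 11 varying members higher and 10 lower (median 0.00, camera pointing up, adjusted p = 0.439), and the 2 members at an unadjusted p under 0.05 were Crp, C-reactive protein, at +1.26 (SE 0.31, adjusted p = 0.320) and Orm1 at +1.57 (SE 0.48, adjusted p = 0.347). Inflammatory signalling had 3 higher and 5 lower, 1 lower at an unadjusted p under 0.05, with a median of -0.29 and no call (camera adjusted p = 0.252, and 0.978 pointing down over the 8 varying members alone). Without control 2, whose mean for inflammatory signalling stood far above the other controls, camera called both lists up, with medians of 0.08 for the acute phase and 0.12 for inflammatory signalling (adjusted p = 0.0248 for each, and 0.306 for each with an estimated correlation), but over varying members alone only the acute phase (adjusted p = 0.0378 against 0.756). Without L. brevis 1, Crp passed the threshold (+1.54, adjusted p = 0.0281). The adhesion molecule gene Vcam1 stood at -0.50 (SE 0.17) and Il1b at +0.45 (SE 0.22). Interferon-stimulated genes had 6 higher and 10 lower, 4 lower at an unadjusted p under 0.05 (median -0.07, or 0.029 without control 2, camera adjusted p = 0.793, and 0.70 pointing down over the 16 varying members alone), with Ifi44l at -0.56 (SE 0.16) and Stat2 at -0.63 (SE 0.18). The other varying probe set of Stat2 gave -0.22 (SE 0.07).

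Oxidative phosphorylation came nearest to the threshold among the lists that missed it, with 17 varying genes higher and 6 lower, 7 and 2 of them at an unadjusted p under 0.05, and a median of 0.16 (camera adjusted p = 0.0635, and 0.707 with an estimated correlation). Over its 23 varying members alone it passed (adjusted p = 0.0201, and 0.940 with an estimated correlation). Atp5pb, of ATP synthase, differed by +0.95 (SE 0.23, adjusted p = 0.323) and Sdhb, of succinate dehydrogenase, by +0.34 (SE 0.09). With the GAPDH 5' minus 3' signal as a covariate this median was 0.02, and under quantile normalization it was 0.07 with camera pointing down (adjusted p = 0.00595, and 0.801 with an estimated correlation). The list was called up in the fit to varying probe sets (adjusted p = 0.0280), without dim probe sets (0.0181), without the intensity trend (0.0427), without control 2 (median 0.20, adjusted p = 0.00875), without L. brevis 2 (median 0.18, adjusted p just under 0.05) and with the replicate block (0.0114). With an estimated correlation these calls were lost (adjusted p = 0.985, 0.583, 0.728, 0.370, 0.703 and 0.705 with an estimated correlation). Ribosomal proteins had 10 higher and 10 lower, 4 higher at an unadjusted p under 0.05 (median 0.03, or -0.017 without L. brevis 1, camera pointing up, adjusted p = 0.30, but down under quantile normalization, 0.000998, and 0.801 with an estimated correlation), with Rpl14 at +0.36 and Rpl24 at +0.18. Xenobiotic metabolism had 14 higher and 7 lower, 1 at an unadjusted p under 0.05 (median 0.13, camera adjusted p = 0.234, but 0.0432 without dim probe sets, and 0.583 there with an estimated correlation). Its median ran from 0.039 without L. brevis 4 to 0.24 without L. brevis 1 and was -0.11 with the GAPDH covariate. On all 8 arrays Cyp3a18 stood at +0.82 (SE 0.33), or +1.14 and past the threshold without L. brevis 1, and Cyp2a1 at +0.72 (SE 0.33). Growth hormone and sex-biased genes had 10 higher and 7 lower, none at an unadjusted p under 0.05 (median 0.10, camera adjusted p = 0.381, but 0.0432 with a median of 0.14 without control 4, and 0.664 there with an estimated correlation). The median was -0.029 without control 2 and -0.045 with the GAPDH covariate, and just below 0 without L. brevis 4. On all 8 arrays Slco1a1 stood at +0.74 and Hao2 at +0.30, or +0.069 without control 2.

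The unfolded protein response had 3 varying members higher and 14 lower, 1 of each at an unadjusted p under 0.05 (median -0.08, camera adjusted p = 0.622, but called down under quantile normalization, median -0.13 and adjusted p = 0.00595, and 0.841 with an estimated correlation), with the ubiquitin ligase partners Herpud1 at +0.69 (SE 0.22) and Syvn1 at -0.58 (SE 0.20). Oxidative stress genes had 11 higher and 3 lower, 1 of each at an unadjusted p under 0.05 (median 0.18, but -0.10 with the GAPDH covariate, camera adjusted p = 0.622), with Osgin1 at -1.60 (SE 0.55) and Sod2, mitochondrial superoxide dismutase, at +0.17. Heat shock and immediate early genes had 7 in each direction, 1 higher at an unadjusted p under 0.05, with a median of -0.00, a mean of +0.13 and camera pointing up (adjusted p = 0.30, but 0.0222 with a median of 0.09 without L. brevis 3, and 0.814 there with an estimated correlation). Dusp1 stood at +1.14 (SE 0.40), with +0.05 at its other probe set, and Gadd45a at +0.68. Cell cycle genes had 1 higher and 3 lower varying members (median -0.07, camera pointing up, adjusted p = 0.757), with Pcna at +0.24, the member at an unadjusted p under 0.05, and Mki67 at -0.14. Clock genes had 10 higher and 5 lower, 1 lower at an unadjusted p under 0.05 (median 0.12, camera adjusted p = 0.527). The median was -0.022 without L. brevis 4, -0.016 without control 1 and 0.35 without L. brevis 2. On all 8 arrays Nfil3 stood at -0.96 (SE 0.39) and Per2 at +0.98 (SE 0.52), or +0.60 without L. brevis 4. The list joins genes that ran in opposite directions across the rats, such as Dbp and Npas2, so its median and camera could miss a shift in clock phase. A score, the mean of 9 genes such as Dbp less that of 5 such as Npas2, ran from -1.12 to 0.92 in control rats. In L. brevis rats it ran from -1.07 to 2.54, and its difference between diets was not tested.

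**Figure D3:**
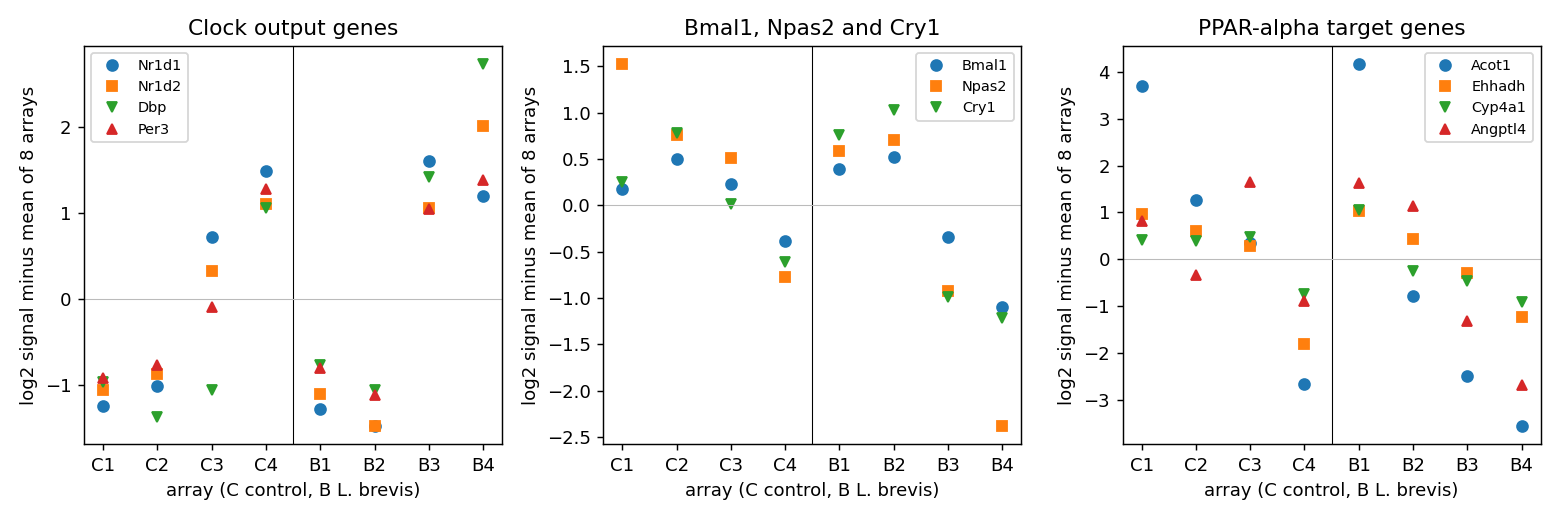
Log2 signal of clock output genes, of Bmal1, Npas2 and Cry1, and of PPAR-alpha target genes in each of the 8 livers, as the difference from the gene's mean over the 8 arrays (the vertical line parts the diets). Control 4, L. brevis 3 and L. brevis 4 share high Dbp (8.19, 8.56 and 9.87) and low Npas2 (7.25, 7.10 and 5.64).

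Signs of RNA and labelling quality differed between the diets. None passed after adjustment over 8 measures, which exact tests of 4 against 4 arrays could hardly do. The 5' minus 3' signal of GAPDH, which is lower where transcripts are broken, was -2.41 ± 0.59 in control and -1.28 ± 0.66 in L. brevis arrays (exact p = 0.0857, 0.183 adjusted over 8 measures), and that of actin was -3.47 ± 0.40 and -2.61 ± 0.67 (exact p = 0.0857). The poly-A spikes had a 3' signal of 9.66 ± 0.27 and 8.82 ± 0.38 (exact p = 0.0286, 0.183 adjusted), 1.79-fold lower with L. brevis. They parted the diets completely, with 9.48 to 10.05 in control and 8.28 to 9.15 in L. brevis arrays. That exact p is the smallest possible here, so its adjusted value says little. Their own 5' minus 3' gap was -1.52 ± 0.11 and -1.46 ± 0.16 (exact p = 0.514). The first principal component held 43.0% of the variance. Over the 8 arrays it went with the GAPDH signal (Pearson r = 0.913, permutation p = 0.00214, 0.00321 adjusted over 3 relations, and Spearman rho = 0.905, permutation p = 0.00475), with r = 0.901 without the 2 arrays farthest from the median. Within control r was 0.642 and within L. brevis 0.992, over 4 arrays each.

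**Figure D4:**
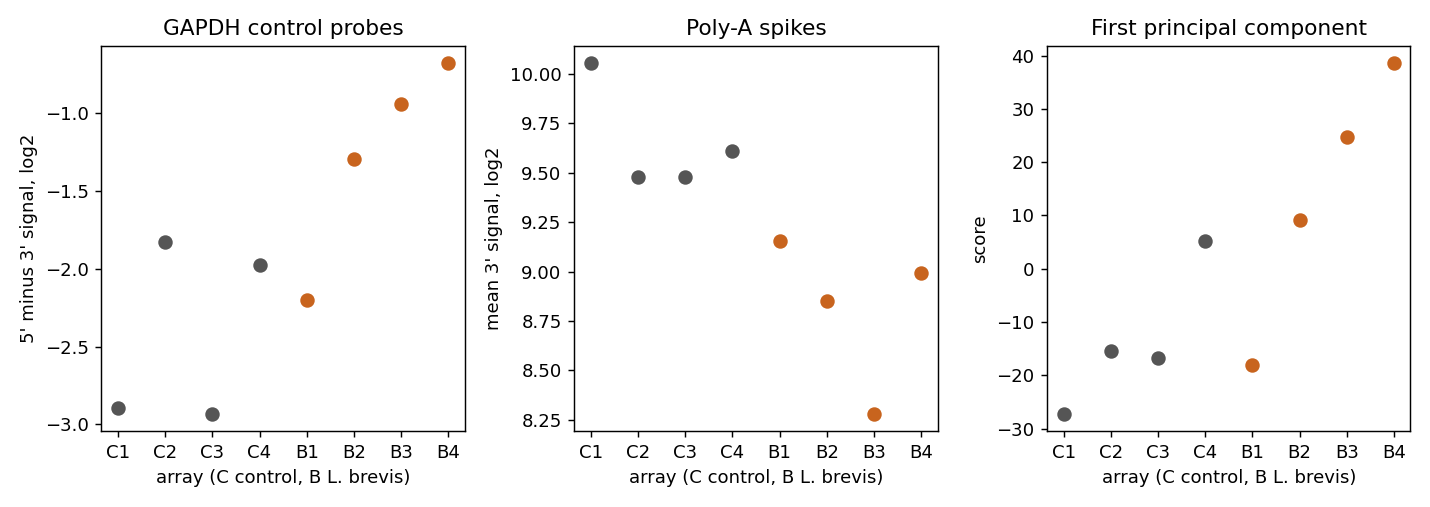
GAPDH 5' minus 3' signal (log2), mean 3' signal of the poly-A spikes (log2) and score on the first principal component, for each of the 8 arrays (grey control, orange L. brevis). L. brevis 1 lies among the control arrays on the first and last of these measures, with a GAPDH value of -2.20 and a component score of -18.1.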

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

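The tests of RNA integrity, of truncation in labelling, of exchanged samples and of the non-parenchymal share, and the splits that count probe sets, were chosen after the result they bear on was seen. The split test of the endothelial list and the clock test were not.

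More varying probe sets than chance gives had an unadjusted p under 0.05 between the diets, 1548 in the fit to varying probe sets. Chance could not be excluded, because 2 of the 35 splits of the arrays into 4 and 4, the real one included, gave as many (highest of the others 2353). Likewise 4 of the 35 gave as many as the 4 calls among varying probe sets (highest other 672). Over all probe sets 2 of the 35 gave as many as the 44 calls (highest other 69). That last count says little, since 37 of the 44 calls fell on probe sets that did not vary, and only 23 of the 69 on varying ones. Truncation in the labelling reaction is argued against by the spiked transcripts, whose 5' minus 3' gap differed between diets by 0.0635 (SE 0.0967), where that of GAPDH differed by 1.13. With the GAPDH 5' minus 3' signal as a covariate the count was 497, under the 632.3 set as the limit, but that signal and the diet were themselves correlated (absolute r = 0.721), so a difference in RNA integrity and an effect of the diet cannot be told apart. A biological effect of the diet stays open as well.

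Of the 35 splits, the one that set control 4 beside L. brevis 2 to 4 and L. brevis 1 beside control 1 to 3 called the most varying probe sets, 672 against 4 for the diets, which points to a structure of the samples, and the first principal component of the same values gives this division too, so it is no separate evidence for it. A phase difference of the liver clock as the whole cause is argued against, since 849 probe sets stayed at an unadjusted p under 0.05 for this split with a score of clock genes as a covariate, above the limit of 632.3. With the GAPDH signal as a covariate 377 stayed, but the split and that signal were correlated (absolute r = 0.792), so RNA integrity and another property of these livers cannot be told apart. An exchange of control 4 and L. brevis 1 after the spikes were added was not decided either: the poly-A spike difference was -0.61 (SE 0.331) with both exchanged and -0.84 as the labels stand. The time of day of sampling is not given in the sources used here, and no biological explanation of this split beyond the clock was tested.

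The lower endothelial markers had a camera p of 0.000316, but 3 of the 35 splits, the real one included, gave one as small (smallest of the others 5.33e-05), so chance could not be excluded. In 23 of the 35 splits camera called more of the 29 lists than the 1 it called for the diets, up to 11. Macrophage markers at +0.16 and stellate markers at -0.02 were not lower by as much, as a smaller share of all non-parenchymal cells would make them. The endothelial mean less the mean of these 2 lists differed by -0.46 between L. brevis and control (exact p = 0.0286). However, the endothelial list had been singled out by its difference in the same rats, and that p is the smallest the design allows. Lymphocyte markers (mean -0.51, which cannot be read as a level of lymphocytes) were left out, so a smaller share was not decided. With the GAPDH signal as a covariate the median was -0.36 and the list stayed past the threshold (camera adjusted p = 0.00897). However, this call, like the one without the covariate, was lost with an estimated correlation (adjusted p = 0.968 with an estimated correlation). The GAPDH signal and the diet were also correlated (absolute r = 0.721), so RNA integrity as the cause was not decided. A change in endothelial cells or their genes with the diet remains a hypothesis beside chance and the other explanations named here.

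Single rats stood far from the other 3 of their group in 19 of 240 groups of 4 tested, where chance gives about 12. In control, Rasa1 was 8.08 in control 4 (others 7.49 to 7.59), Dhcr7 was 7.92 in control 4 (others 8.62 to 8.72), Inhba was 8.29 in control 4 (others 8.49 to 8.53), Loxl2 was 6.91 in control 4 (others 6.71 to 6.74) and Cldn7 was 5.93 in control 4 (others 6.10 to 6.14). Control 1 had 8.003 for Cpd (others 8.45 to 8.53) and 9.04 for Icoslg (others 9.18 to 9.21). In the L. brevis group, rat 1 had 8.38 for Cyp7a1 (others 11.50 to 11.98), 10.16 for Crp (others 11.23 to 11.37), 8.04 for Slc25a28 (others 7.69 to 7.73) and 7.73 for Wdr81 (others 7.82 at the nearest). L. brevis 2 had 11.51 for RT1-Ba (others 6.20 to 6.43) and 8.59 for RT1-Bb (others 6.18 to 6.39). L. brevis 3 had 6.90 for Prkch (others 7.04 to 7.05), and L. brevis 4 had 10.80 for Sar1b (others 10.85) and 10.38 for Apmap (others 10.43 to 10.44). Of the list means, relative to the mean of all arrays, inflammatory signalling was 1.01 in control 2 (others -0.32 to -0.11), lymphocyte and antigen presentation markers were 0.50 in L. brevis 2 (others -0.60 to -0.44) and ribosomal proteins were 0.056 in control 2 (others -0.071 to -0.058). The lymphocyte list includes RT1-Ba and RT1-Bb. At another probe set of each of these genes L. brevis 2 was the lowest of its group (4.38 and 5.31), while a further RT1-Ba probe set was high there (11.9).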

How the results depend on the processing

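The fits to varying probe sets, with the GAPDH covariate, on matched arrays and without L. brevis arrays 3 and 4 were chosen after the data were seen. Counts of calls depended on the processing. Most calls fell on probe sets that did not vary, and of these 24719 quantile normalization gave 11444 and median centring 24718 a range over 0.01 log2. Against 17 higher and 27 lower (3644 at an unadjusted p under 0.05), limma called 0 and 0 under quantile normalization (3374) and 0 and 0 under median centring (1694), while removal of dim probe sets left 8 higher. Array weights, largest for L. brevis 3 (3.36) and smallest for L. brevis 1 (0.32), gave 30 higher and 47 lower (6065), and rank product 704 and 616. The fit to varying probe sets gave 0 and 4 (1548), the GAPDH covariate 0 and 0 (497), the 3 arrays matched on that signal (control 2, control 4 and L. brevis 1, a lone sample assumed to vary like the control) 0 and 0 (413), and the fit without L. brevis 3 and 4 gave 0 and 0 (610). The last 3 fits had an added term or fewer samples and covered the varying probe sets alone. Leaving out each replicate gave 30 to 89 higher, the most without L. brevis 1, 35 to 91 lower and 2533 to 4804 at an unadjusted p under 0.05. The cause of these differences was not tested.

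No pairing of the rats by replicate number is stated, and the values left it open whether same-numbered rats shared something. They correlated at 0.359, 0.203, 0.0778 and 0.381, all positive, and 5 of the 8 samples correlated best with their own number. The main fit had no block, a choice fixed before the data were examined because no pairing was stated, and it was kept. A fit with the replicate block gave 62 higher and 66 lower (3128) and also called Fam171a1, Inhba, Acaca, Sod2 and oxidative phosphorylation (adjusted p = 0.0114, and 0.705 with an estimated correlation). Icoslg ranged from -0.95 to -0.74 and Krt79 from -0.63 to -0.54 over the alternatives. Both lost the call under quantile normalization, median centring, the block, the GAPDH covariate and the fit without L. brevis 3 and 4, and Icoslg also without any 1 of control 2, 3 or 4 or L. brevis 2, 3 or 4 (adjusted p up to 0.0703).

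The endothelial median was negative under every alternative run, from -0.50 to -0.25 with each replicate left out. Its call was lost with an estimated correlation and fry (-0.41 in each), without L. brevis 3 and 4 (-0.35, adjusted p = 0.0572) and without control 1 or L. brevis 1. Exact permutation (-0.41) gave the smallest p the design allows, which adjustment over 29 lists could hardly leave past the threshold. With 1 choice changed at a time the adjusted p ran from 3.40e-05 to 0.707, and up to 0.996 where an estimated correlation was joined to another alternative. The median moved most without control 2 (-0.25). Quantile normalization turned camera's direction to a call downwards for cholesterol ester and lipoprotein (median -0.095), PPAR-alpha targets (-0.19), hepatocyte secretory proteins (-0.018), oxidative phosphorylation (0.066) and ribosomal proteins (-0.055). The 3 matched arrays set 1 L. brevis rat against 2 control rats, so their values (endothelium -0.27, PPAR-alpha targets 0.90, erythroid markers -0.61) compare single rats and say nothing of the diets or of how stable a call is. None of the 40 list calls made by camera in these fits held with an estimated correlation, 28 held over varying members alone (none of those under quantile normalization), and the median of 17 of the 29 lists changed sign with 1 rat left out. Of 638 list results 507 kept both direction and side of the threshold, 99 changed direction with no call on either side, 6 reversed with a call, 19 gained a call and 7 lost one. Of 1657 gene results 1574 kept both, 41 changed sign without a call, 24 gained a call and 18 lost one. Quantile normalization also called the unfolded protein response down (-0.13). PPAR-alpha targets were called up with the GAPDH covariate (0.55) and without L. brevis 3 and 4 (0.21), where heat shock genes (0.38) and ribosomal proteins (0.07) were called up too. The share of higher among varying probe sets at an unadjusted p under 0.05 was 41.2% as deposited, 41.0% after quantile normalization and 43.1% after centring. A log offset was not run because the values are log2, and the robust trend has no list test.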

Other observations

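The genes and probe sets in this part were chosen after their values were seen, and the differences between single rats given here were not tested. Clock genes differed between rats of one diet. Control 4, L. brevis 3 and L. brevis 4 had the highest Dbp and the lowest Npas2 of the 8. Dbp was 8.19, 8.56 and 9.87 in those 3 rats and 5.77 to 6.37 in the others, and Npas2 was 7.25, 7.10 and 5.64 against 8.53 to 9.55. Control 3 lay nearer to them on Nr1d1, at 7.86 against 8.34 to 8.74 in the 3 rats and 5.66 to 6.12 in the other 4, and between the groups on Nr1d2 (9.08), Per3 (6.87) and Tef (8.15). In the same 3 rats targets of PPAR-alpha were low, with Acot1 at 5.18, 5.34 and 4.27 against 7.05 to 12.00 and Ehhadh at 10.82, 12.33 and 11.40 against 12.90 to 13.65. Thrsp, a gene of lipogenesis, was 9.70 in control 4 and 9.40, 9.61 and 11.46 in L. brevis 2 to 4, against 7.03 to 8.09 elsewhere. No correlation is given, since most rats fell into separate clusters on these genes.

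Several genes were high or low in single rats by several log2 units. Skeletal muscle genes were high in L. brevis 2 alone: Acta1 was 12.45 there and 5.08 to 5.54 elsewhere, Myh8 was 11.38 against at most 6.03, Myl1 10.51 against at most 5.73 and Tnnc2 10.09 against at most 6.59. Both probe sets of Ugt2b were almost without signal in control 4, at 2.20 and 1.66, against 13.16 to 14.03 and 9.78 to 12.15 in the other rats. Hamp, the iron hormone hepcidin, ran from 5.77 in control 1 to 14.69 in control 3. Hsd17b2 was 15.22 in L. brevis 4 and 6.29 in L. brevis 1.

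Probe sets of the major histocompatibility region divided the rats across the diets. The brightest RT1-Ba probe set was 6.13 to 6.43 in control 3 and L. brevis 1, 3 and 4, and 10.21 to 12.11 in control 1, 2, 4 and L. brevis 2. Another probe set of that gene went the other way, with 11.44 to 11.81 in the first 4 rats, 4.23 to 4.38 in control 2, 4 and L. brevis 2, and 10.37 in control 1, which was high on both. Fam111a was 8.86 to 11.18 in the first 4 rats and 4.80 to 5.12 in the others. In all, 165 probe sets had a range over 3 log2 units, and the diets did not overlap in 5 of them, where chance gives 2.86% of probe sets.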
